A study of Mus musculus with 57 samples.

How the data were processed

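Single cells from the kidneys of Crym-EGFP mice at postnatal day 4 were profiled by RNA sequencing. In these mice a bacterial artificial chromosome places the green fluorescent protein EGFP under the control of the Crym gene. Per the labels' protocols, kidneys were minced, digested with trypsin, filtered and sorted by fluorescence, and the sampled structure was the renal vesicle, the first epithelial stage of the nephron. Cells were captured on a Fluidigm C1 chip, whose chambers were inspected under the microscope for the presence of a single cell. Complementary DNA was made and amplified with the SMARTer kit, and libraries were made with the Nextera XT kit, which keeps no strand and adds no molecular identifiers. The labels give 57 cells, all from 1 pool of 2 kidneys, of unknown sex and mixed strain background. The number of animals behind the pool is not given in the sources used here.

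The authors deposited a table of 12087 genes in 57 cells whose values are RPKM, reads per kilobase of gene scaled by the number of mapped reads, not logged, per the file headers. The same table counts for each gene the cells above RPKM 3. That count equalled the values in all 12087 genes and was never below 2, so a gene below that level in nearly every cell had no row. A smaller table deposited by the authors holds RPKM values of 787 genes in 28 of the cells, together with a signed fold between a proximal and a distal class, per the file headers. This fold is treated as a score of the authors, positive where the proximal class was higher and negative where the distal class was higher. Neither the formula of the fold nor the class of each cell is given in the sources used here. The submitters' processing notes name TopHat 1.4.1, DESeq and the mouse build mm9 without stating what each was used for. Coordinates are printed as the deposited tables give them, on build mm9 per the submitters' processing notes. The RPKM values of the same genes and cells differed between both tables, so the tables were never mixed within a comparison.

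The cells form 1 group and come from 1 pool, so cells were not treated as replicates and no p-value was computed from them. The detection threshold, gene lists, tests, rule for named genes and most of the alternative settings were fixed before the data were examined. A gene was called detected in a cell at RPKM 1 or more. Shares of cells carry exact Clopper-Pearson 95% intervals, which cover the sampling of cells from this pool alone. Means and SDs of RPKM were taken over all 57 cells. For each of 24 gene lists, with 329 entries in all, the number of cells with at least 2 detected members was counted. Of these entries, 246 had values that could be analysed, and the others were not analysed here. The median share of cells over the members was placed among 10000 random lists of the same size, drawn for each member from the 50 genes nearest in mean RPKM. Joint detection of a pair of lists was set beside the number that independence gives and beside 10000 pairs of random lists matched on the number of detecting cells, leaving out genes held by both lists. Coherence was the mean pairwise Spearman rho across cells of the members detected in at least 5 cells, placed among 10000 lists matched in the same way. A percentile describes these libraries and is not a test.

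The gene lists covered nephron progenitor, renal vesicle, distal and proximal renal vesicle, podocyte, proximal tubule, loop of Henle and distal tubule, parietal epithelium, ureteric bud and collecting duct, renal stroma, endothelium, immune cells, erythroid cells, mesangial and smooth muscle cells, G2/M phase, S phase, immediate early and dissociation stress, housekeeping, Y-linked genes, X inactivation, the Notch, Wnt, and FGF and BMP pathways, and Hox genes. In each list the text names the 4 members detected in most cells, with ties broken by mean RPKM, and the member detected in fewest. A fixed set of developmental genes, with Crym, Six2, Wt1 and Pou3f3 among them, is named wherever it had values. The rule for the classes ranked genes by their difference between classes. Because the class of each cell is not given, the 12 genes with the largest deposited fold in each direction are named instead, with members of the proximal and distal lists. Clusters are described by the 8 genes with the largest difference in mean log2(RPKM + 1). The first 12 overdispersed genes and the 10 genes with the highest median RPKM are named too. A few genes that the rule takes are not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

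Cells were clustered by Ward's method on log2(RPKM + 1) of the 500 most variable of 10083 genes with mean RPKM of 1 or more that were detected in at least 5 cells. The number of clusters, from 2 to 6, was the one with the highest mean silhouette. Overdispersion was the squared coefficient of variation above a lowess trend on mean RPKM with span 0.3, among genes with mean RPKM of 10 or more. No doublet caller was run, since the number of cells is small and chambers had been inspected. As a substitute, results were repeated without the tenth of cells with the most detected genes. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, statsmodels 0.14.6 and matplotlib 3.10.9.

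Read numbers were not among the values used, and depth was estimated from the low RPKM values. In 6056 of 10390 genes that could be examined (58.3%), the values were whole multiples of a smallest step once the depth of each cell was allowed for. In these genes 98.0% of the low values, up to 10 reads, lay within 0.05 of a whole number. The relative depth of the cells ranged from 0.345 to 1.66. An approximate absolute scale came from 2251 genes with a single reference transcript and gave 0.480 to 2.31 M reads per cell with a median of 1.49 M (M, mega). The quartiles of the gene lengths behind that scale put the median cell anywhere from 1.46 to 2.74 M reads. On the approximate scale 1 read in a gene of 2 kb was worth RPKM 0.336 in the median cell and 1.04 in the shallowest cell. A value below RPKM 1 could therefore be 1 or 2 reads, and detection of weakly expressed genes depended on the capture of few molecules. The lengths came from a reference annotation of another mouse build, which served for nothing else.

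Each computation was tested on simulated data before use. With 12087 simulated genes a planted coherent list reached percentile 100, and 2 lists with nothing planted reached 42.7 and 66.7. A planted pair of opposed lists reached percentile 0 for joint detection, and a pair with nothing planted reached 58.6. That check says little about lists that are each found in most cells, because their joint count is then nearly fixed. Among 5641 genes tested, 166 of 200 genes raised 4-fold in overdispersion were ranked in the leading 200. A planted pair of cell groups with a strong contrast was recovered with an adjusted Rand index of 1 when 2 clusters were asked for, which says little about weak partitions. In the checks of lists and clusters each gene was shuffled over cells, so differences in depth between cells were not part of them. In 6000 simulated genes 99.97% of the low values were given the read count they had been made with.

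Alternative settings fixed beforehand were detection above 0 and at RPKM 5, the loss of cells more than 3 scaled MADs from the median number of genes, the loss of the tenth of cells with the most genes, 1 or 3 members per list, Pearson's r, members detected in at least 10 cells, the number of detected genes regressed out, pseudocount 0.1, 1000 or all genes for clustering, k-means, other overdispersion measures and scaling by the upper quartile. Those for the classes needed the class of each cell and were not run. Added after the data were seen were the loss of the 7 cells with Pax8 below RPKM 5, clusterings into 3 and 5 clusters, and a list of imprinted growth genes. No column of either table belonged to a sample outside the series.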

Results

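Transcriptomes of 57 single cells sorted as renal vesicle cells from 1 pool of 2 kidneys of Crym-EGFP mice at postnatal day 4 were described. The renal vesicle forms when progenitors of the cap mesenchyme become epithelial, and its proximal and distal parts later give rise to the glomerular and tubular segments of the nephron. The stated aim of the series was an atlas of gene expression in the developing kidney, and the design holds a single group of cells. A smaller table of the authors sets a proximal class of cells against a distal class. The estimated depth was 0.480 to 2.31 M reads per cell, with a median of 1.49 M. There were no replicate pools, so SDs are given over cells, and intervals on shares of cells are exact Clopper-Pearson 95% intervals.

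The cells shared a small common set of transcripts and differed widely beyond it. A median of 4307 genes was detected per cell at RPKM 1 or more, with quartiles of 3815 and 4746 and a range of 2809 to 6502. In every cell 306 genes were detected, 2.53% of the 12087, while 3390 genes (28.0%) were detected in at least 29 cells and 2245 (18.6%) in 5 cells or fewer. The highest median RPKM belonged to the translation elongation factor Eef1a1 (5937), the locus LOC100503946 (4278), ubiquitin B (Ubb, 3609), beta-actin (Actb, 3528), Ppia (2945), Gm1821 (2775), the histone variant H2afz (2666), prothymosin alpha (Ptma, 2389) and the ribosomal protein genes Rpl41 (2111) and Rps14 (1938). Genes such as LOC100503946, Ppia, Gm1821 and the ribosomal genes have near-identical copies in the genome that can share reads. Copies were not examined for any gene named here, so all of these levels are uncertain. The rank correlation between pairs of cells, across genes, had a median of 0.425 and ranged from 0.286 to 0.542, and genes are not independent replicates.

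Nearly all cells carried transcripts of the early nephron. The Notch ligand Jag1 (chromosome 2, 136907194 to 136942067, build mm9) was detected in 56 of 57 cells (98.2%, interval 90.6 to 99.96) at a mean RPKM of 219 ± 192 (SD, n = 57 cells). The cyclin Ccnd1 was detected in 55 cells (mean 426 ± 329) and the renal transcription factor Pax8 (chromosome 2, 24276080 to 24331086) in 52 cells (91.2%, interval 80.7 to 97.1) at a mean of 312 ± 280. The Notch target Hes1 was detected in 46 cells and the transcription factor Lhx1 in 45 (78.9%, interval 66.1 to 88.6, mean 77.4 ± 92.9). Wnt4, a signal that drives the mesenchyme to become epithelial, was found in 19 cells (33.3%, interval 21.4 to 47.1) at a mean of 20.3 ± 49.3, and Fgf8 was the least widely detected member with 6 cells. All 57 cells had at least 2 of the 16 renal vesicle genes, among them the 7 cells with Pax8 below RPKM 5, so this count cannot tell nephron cells from others. In cell 1, macrophage-like by the markers described below, Jag1 was at RPKM 6.21 and Ccnd1 at 8.25. The median share of cells over the members, 33.3%, lay at percentile 1.2 of random lists of like expression (22.1 with detection above 0 and 6.16 at RPKM 5).

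Of the progenitor genes, Six2, Cited1, Osr1, Hoxa11 and Itga8 were among those detected in few cells, while Sall1 and Tmem100 were found in most. Six2, which maintains the progenitor state, was detected in 5 cells (8.8%, interval 2.9 to 19.3) with a highest RPKM of 17.9, and Cited1 in 4 cells (7.0%, interval 1.9 to 17.0), with RPKM 130 in cell 8 and 34.1 or less in the other cells. A single cell, number 12, had both. Osr1 was found in 2 cells. Other members of the same list were more widespread, with Sall1 in 46 cells (mean 63.8 ± 70.8), Tmem100 in 31, Uncx in 22 and Eya1 in 19, and 46 cells (80.7%, interval 68.1 to 89.95) had at least 2 of the 12 progenitor genes analysed. The median share of cells over these genes, 11.4%, lay at percentile 27.9 of random lists. Crym itself (chromosome 7, 127329898 to 127345502), the gene that drives the reporter, was detected in 7 cells (12.3%, interval 5.1 to 23.7), with RPKM 1.98 in the lowest of them and 101.6 in the highest. The reporter's own RNA was not analysed here, and at this depth a gene below RPKM 1 cannot be taken as absent: the housekeeping genes Tbp and Hprt were detected in 31 and 46 cells.

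**Figure D1:**
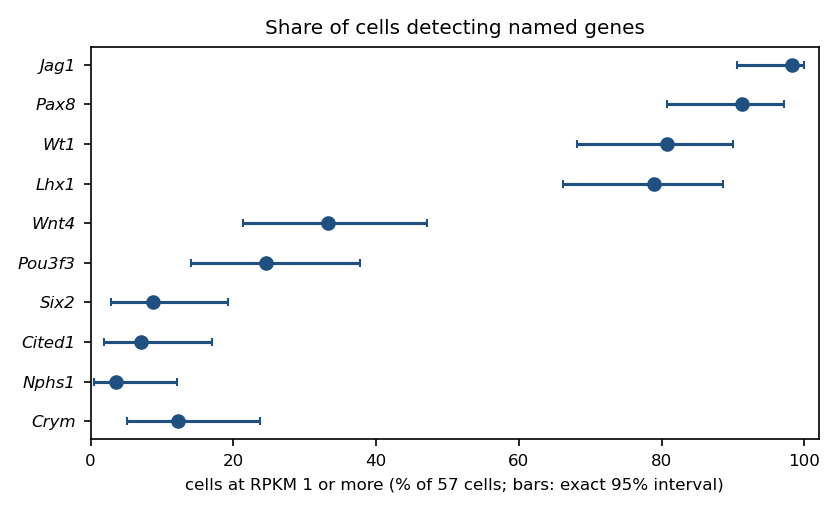
Share of the 57 cells with RPKM 1 or more (x axis, percent) for 10 developmental genes (y axis), with bars for the exact 95% interval over cells. Jag1 and Pax8 exceed 90%, Wt1 and Lhx1 lie near 80%, and Six2, Cited1 and Nphs1 lie below 10%.

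Proximal and distal renal vesicle genes were both present in most cells. The lists were detected together about as often as independence gives, though under most settings in fewer cells than matched random lists. In the main setting this joint count was nearly fixed, since each list alone was found in most cells. Wt1 (chromosome 2, 104966686 to 105013771), a transcription factor of the proximal vesicle and podocyte, was detected in 46 cells (80.7%, interval 68.1 to 89.95) at a mean RPKM of 178 ± 272. Other proximal members were Cited2 in 35 cells, Tcf21 in 33, Tmem100 in 31 and, least often, Podxl in 4. On the distal side Jag1, Ccnd1 and Lhx1 were widespread and Greb1 was found in 24 cells, whereas Pou3f3 (chromosome 1, 42753991 to 42757054) was detected in 14 cells (24.6%, interval 14.1 to 37.8) with a median RPKM of 0 and a maximum of 271, and Tfap2b in 2. At least 2 members were detected in 52 cells for the proximal list and in 55 for the distal list, and the median shares of cells over their members were 46.5% and 29.8%, at percentiles 8.90 and 0.660 of random lists. These percentiles were 15.6 and 13.6 with detection above 0 and 13.0 and 5.52 at RPKM 5.

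Both lists were detected together in 51 cells (89.5%, interval 78.5 to 96.0), where independence gives 50.2 and matched random lists gave a median of 56, placing the pair at percentile 0.005. The percentile depended on the setting, rising to 6.26 with 1 member of each list asked for and to 51.2 with detection above 0, where all 57 cells had both lists. Against independence the joint count was not lower in any setting fixed beforehand, with 44 cells against 41.2 for 3 members and 41 against 38.7 at RPKM 5. The low percentile therefore does not show that the lists avoid each other within cells. Nor does the main count show that they meet freely: with the lists in 52 and 55 of 57 cells, it was nearly fixed. Members of the distal list rose and fell together across cells, with a mean Spearman rho of 0.354 (percentile 100), and those of the proximal list less so (0.105, percentile 98.9). Between the lists the mean rho was 0.0053 (percentile 7.05). In pairs of genes chosen after their values were seen, Wt1 and Sox9 at RPKM 20 or more met in 2 cells against 7.58 from independence, and Wt1 and Pou3f3 at that level in 1 cell against 5.05, whereas Wt1 and Lhx1 at that level met in 22 cells against 22.7. At RPKM 1 or more the gap was smaller, with 11 cells against 13.7 for Wt1 and Sox9, 9 against 11.3 for Wt1 and Pou3f3 and 37 against 36.3 for Wt1 and Lhx1, and Tmem100 and Sox9 at RPKM 5 or more met in 8 cells against 7.86. Without the 7 cells with Pax8 below RPKM 5, a setting chosen after the data were seen, the mean rho between the lists was -0.067 (percentile 0) and that within the proximal list was 0.049 (percentile 69.1), so the coherence of the proximal list rested on those cells.

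**Figure D2:**
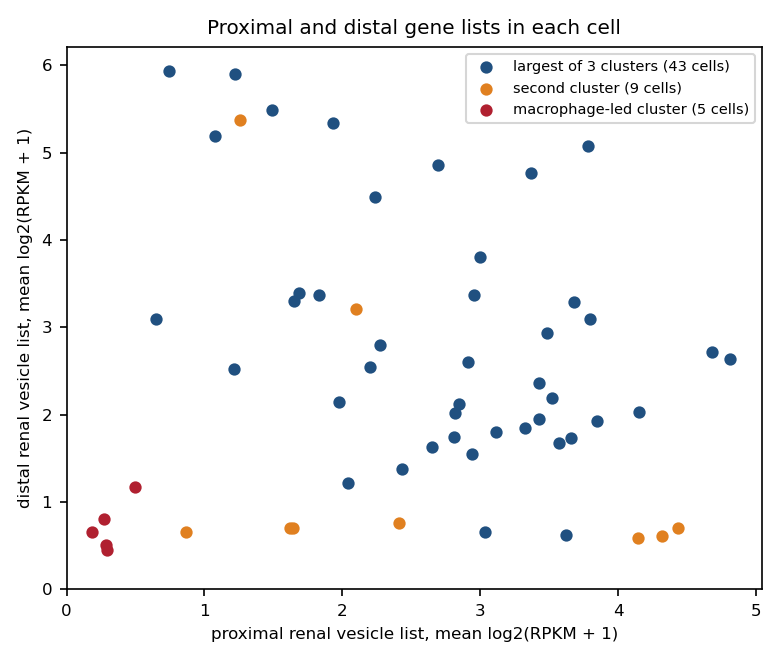
Mean log2(RPKM + 1) of the proximal (x axis) and the distal (y axis) renal vesicle list in each of 57 cells, 1 point per cell, coloured by membership in 3 clusters. The 5 macrophage-led cells lie near the origin, and the cell with the highest distal mean, 5.94, has a proximal mean of 0.74.

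Of the genes listed for later nephron segments, several were found in most cells, and the slit diaphragm gene Nphs1 and most proximal tubule genes in few. In the podocyte list Wt1 and Cd2ap were detected in 46 cells each, the cell cycle inhibitor Cdkn1c in 44 and Dach1 in 41. The slit diaphragm gene Nphs1 (nephrin) was detected in 2 cells (3.5%, interval 0.4 to 12.1), at RPKM 27.9 in cell 2 and 24.8 in cell 10. At least 2 podocyte genes were found in 56 cells, and 5 of the list's genes are also in the proximal renal vesicle list. In the loop of Henle and distal tubule list Wfdc2 was detected in 37 cells, Emx2 in 23, Atp1b1 in 20, Irx3 in 8 and Tfap2b in 2, and 28 cells (49.1%, interval 35.6 to 62.7) had at least 2 members. The proximal tubule list was sparse, with Dab2 in 22 cells, Gatm in 13, Pdzk1 in 10 and Miox in 2, and 14 cells (24.6%, interval 14.1 to 37.8) had at least 2 members. These 14 included the 5 macrophage-like cells described below, in which Gatm was between RPKM 601 and 1861 and Dab2 between 40.9 and 204, and 8 cells (16%) remained without the 7 cells with Pax8 below RPKM 5. Its median share of cells, 3.51%, lay at percentile 0.080 of random lists (2.03 with detection above 0 and 6.20 at RPKM 5), against 81.4 for podocyte and 64.5 for distal tubule genes. These percentiles rest on the members analysed, 7 of 20 proximal tubule, 18 of 20 podocyte and 6 of 18 distal tubule genes. In the parietal epithelium list Ncam1 was detected in 53 cells, Lhx1 in 45, Prom1 in 19, Cldn1 in 9 and Cp in 3, with 46 cells having at least 2 members. In the ureteric bud and collecting duct list Hoxb7 was detected in 24 cells, Cdh16 in 13, Krt18 in 9 and Wnt11 in 4, with 13 cells having at least 2 members. Hnf4a, Slc12a1, Foxd1 and Ret were not analysed here.

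In the 4 other pairs of lists, joint detection in single cells lay within the range of matched random lists in the main setting, but not in every other setting. Podocyte and proximal tubule genes were found together in 13 cells, where independence gives 13.8 and random lists a median of 13 (percentile 46.9). Of these 13 cells 4 were macrophage-like, and 8 cells remained without the 7 cells with low Pax8. Podocyte and distal tubule genes met in 28 cells (random median 30, percentile 17.0), progenitor and podocyte genes in 46 (random median 48, percentile 12.6), and renal vesicle and stromal genes in 47 (random median 49, percentile 20.8). Podocyte genes were in 56 of 57 cells and renal vesicle genes in all 57. Each joint count was thus nearly fixed by the cells of the other list (14, 28, 46 and 47). These percentiles mostly rank how widely that list was detected and cannot show whether lineages meet in 1 cell. Over the settings fixed beforehand, the percentile ran from 29.7 to 63.9 for podocyte with proximal tubule, from 0.025 (1 member) to 91.4 (3 members) for podocyte with distal tubule, from 0.020 (1 member) to 24.3 for progenitor with podocyte and from 0 (3 members) to 32.6 for renal vesicle with stroma. Members of the podocyte list were correlated across cells (mean rho 0.176, percentile 100), as were those of the progenitor (0.098, percentile 99.7), renal vesicle (0.173, percentile 100), distal tubule (0.221, percentile 99.8) and parietal lists (0.146, percentile 99.5). Without the 7 cells with low Pax8 the mean rho was 0.133 for podocyte, 0.054 (percentile 90.6) for progenitor, 0.111 for renal vesicle and 0.099 (percentile 94.5) for parietal genes, so part of these correlations rested on those cells. The proximal tubule and ureteric bud lists showed mean rhos of 0.020 and -0.0022, at percentiles 51.5 and 37.3. Counts of cells with at least 2 members depend on the detection threshold and on the number of members asked for.

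Strong immune transcripts were concentrated in 5 cells, and endothelial and erythroid genes were detected in few. In the immune list C1qb was detected in 16 cells, Lyz2, Cd68 and Ptprc in 15 each and Cd14 in 3, and 18 cells (31.6%, interval 19.9 to 45.2) had at least 2 of its 10 members analysed. The level was very uneven: C1qb, a complement component made by macrophages, was between RPKM 1589 and 2362 in cells 1, 25, 35, 46 and 58 and at most 129 in all others. The immune list was highly coherent (mean rho 0.452, percentile 100), and rho remained 0.293 without the 7 cells with low Pax8. In the stromal list Aldh1a2 was detected in 35 cells, Meis2 in 24, Meis1 in 17 and Fibin in 2. At least 2 stromal members were found in 47 cells, with a mean rho of 0.145 (percentile 99.99), or 0.046 (percentile 78.0) without those 7 cells. In the mesangial and smooth muscle list Acta2 was detected in 16 cells, Tagln in 12, Cspg4 in 8, Itga8 in 7 and Pdgfrb in 3, with at least 1 member in 31 cells, at least 2 in 12 and a mean rho of 0.074 (percentile 88.1). Of the 3 endothelial genes analysed Egfl7 was found in 9 cells and Flt1 and Tek in 2 each, and no cell had 2 of them (upper limit 6.27%). The single erythroid gene analysed, Alas2, was found in 4 cells.

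Most cells carried transcripts of the cell cycle. The S phase genes Tyms, Rrm2, Rrm1 and Slbp were detected in 56, 52, 49 and 49 cells, with Rrm2 at a mean RPKM of 312 ± 390, and Cdc6 in 17. Among G2/M genes Top2a was detected in 54 cells (mean 141 ± 181), the survivin gene Birc5 in 50, Cdk1 in 45, cyclin B1 (Ccnb1) in 36 and Aurka in 14. At least 2 members were found in 57 cells for S phase and 53 for G2/M, and the members went together across cells, with mean rhos of 0.523 for G2/M and 0.395 for S phase (percentile 100 for both). The median shares of cells over the members lay at percentiles 8.10 for G2/M and 4.16 for S phase of random lists, toward fewer cells than genes of like expression. With the number of detected genes per cell regressed out, the mean rho of the G2/M list was 0.385.

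Genes induced by tissue dissociation were present in a part of the cells. Jun was detected in 37 cells, Egr1 in 30 (mean RPKM 86.0 ± 166), Ier2 in 26, Btg2 in 21 and Hspa1b in 3. At least 2 members of the list were found in 41 cells, and its mean rho was 0.236 (percentile 100). The housekeeping genes Eef1a1, Actb, Ppia and Rplp0 were detected in all 57 cells, and the mean rho of that list was 0.041 (percentile 44.4).

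Leading members of the signalling pathways of nephron formation were found in most cells, while the lists as a whole were detected about as widely as random lists. In the Notch list Jag1 (56 cells), the receptor Notch2 (55) and the targets Hes1 (46) and Hey1 (45) led, and Hes5 and Rfng were found in 4 cells each. In the Wnt list Lgr4 (56 cells), the secreted inhibitor Sfrp2 (54), beta-catenin (Ctnnb1, 52) and Tcf7l2 (50) led, and Wnt5a was found in 2. In the FGF and BMP list Id3 was detected in 53 cells, the receptor Fgfr1 in 49, Id2 in 48 and Bmpr1a in 39, and Smad6 and Fgf9 in 4 each. The median shares of cells over the members were 45.6% for Notch, 25.4% for Wnt and 42.1% for FGF and BMP, at percentiles 77.9, 40.4 and 48.9 of random lists. All 57 cells had at least 2 members of each of these pathways, and their mean rhos were 0.137 for Notch (percentile 99.99; random mean 0.028), 0.064 for FGF and BMP (percentile 98.5) and 0.046 for Wnt (percentile 89.6). Hoxa10 was detected in 40 cells, Hoxc10 in 35, Hoxa9 in 24, Hoxd10 in 20 and Hoxa11 in 6, with at least 2 Hox genes in 45 cells and a mean rho of 0.127 (percentile 99.6).

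The authors' own comparison asked which genes separate a proximal from a distal class of renal vesicle cells. Of 787 genes in the authors' deposited table, 436 were higher in the proximal and 351 in the distal class, with 74 and 59 of them at 10-fold or more. The largest proximal folds in the authors' deposited table belonged to Tmem100 (173-fold), the imprinted RNA H19 (115-fold), Wt1 (96.1-fold), the myelin protein gene Pmp22 (65.0-fold), Sncaip (46.6-fold) and the sulfatase Sulf1 (42.4-fold). Further proximal genes in the authors' deposited table were the basement membrane gene Nid1 (38.0-fold), Plat (35.8-fold), the netrin receptor Unc5c (34.5-fold), Prr5l (29.1-fold) and Car12 (28.8-fold). The largest distal folds in the authors' deposited table belonged to Papss2 (220-fold), which makes the sulfate donor of the cell, the transcription factor Sox9 (131-fold), the Notch ligand Dll1 (88.3-fold), Pcdh7 (73.0-fold), the prion gene Prnp (71.0-fold) and the Wnt inhibitor Dkk1 (48.7-fold). They were followed, still in the authors' deposited table, by Tpd52 (43.9-fold), 2900092D14Rik (39.2-fold), the FGF target Etv5 (38.8-fold), Pou3f3 (30.8-fold), Greb1 (28.2-fold) and Rbm47 (26.3-fold). By those coordinates, 2900092D14Rik (chromosome 1, 42757181 to 42760021) begins next to the end of Pou3f3, and reads of overlapping or neighbouring transcripts were not told apart by strand.

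**Figure D3:**
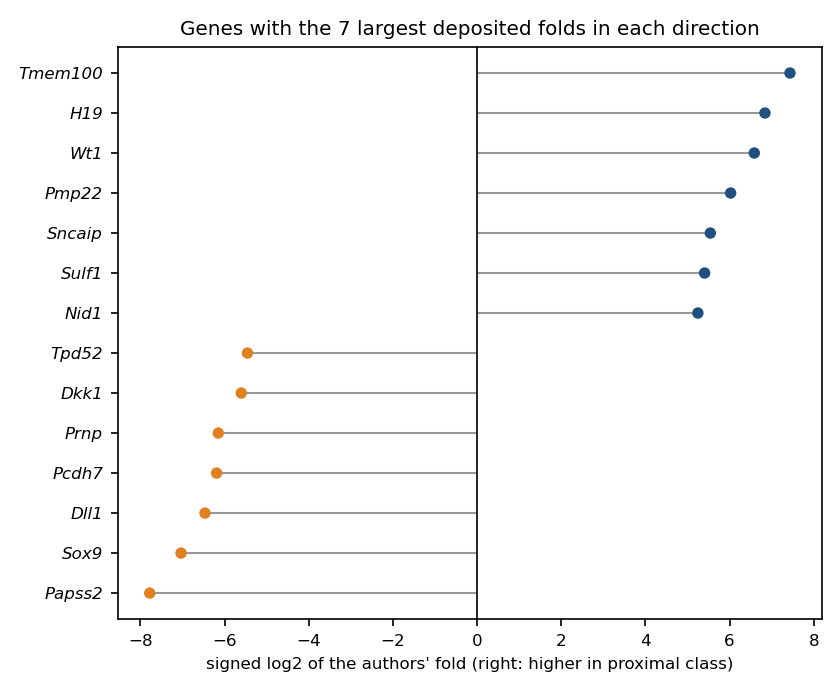
Signed log2 of the fold between classes in the authors' deposited table (x axis) for the 7 genes with the largest fold in each direction (y axis), 1 point per gene. Tmem100 (173-fold) leads on the proximal side and Papss2 (220-fold) on the distal side.

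The distal and proximal renal vesicle lists fell on the side their names give, although the classes came from these same cells and are not independent evidence. Of the 13 distal genes analysed, 9 were in the authors' deposited table, where 0.846 were expected, and all 9 were higher in the distal class, among them Mecom (9.98-fold), Lhx1 (4.90-fold) and Jag1 (2.41-fold). Of the 12 proximal genes 5 were in the authors' deposited table, where 0.781 were expected, all higher in the proximal class, with Efnb2 at 24.9-fold and Foxc2 at 5.96-fold among them. Among FGF and BMP list genes in the authors' deposited table, 7 were higher in the distal class, among them Dusp6 (19.3-fold), Fgfr2 (10.3-fold), Bmp7 (9.67-fold), Etv4 (6.92-fold) and Spry2 (4.20-fold), and 2 were higher in the proximal class, Bmper (6.37-fold) and Id3 (1.88-fold). All 4 Wnt list genes in the authors' deposited table were higher in the distal class, namely Dkk1, Lgr5 (7.84-fold), Lgr4 (2.23-fold) and Sfrp2 (2.21-fold). The Notch list was divided in the authors' deposited table, with Dll1, Hes1 (4.18-fold) and Jag1 higher in the distal and Rbpj (6.33-fold) and Notch2 (2.46-fold) higher in the proximal class. The 3 S phase genes in the authors' deposited table, Gins2 (10.3-fold), Mcm7 (6.38-fold) and Mcm6 (5.87-fold), were higher in the proximal class (0.977 S phase genes expected in that table, percentile 93.7), and the only G2/M list gene there, Cenpf (6.46-fold), was higher in the distal class. Podocyte list genes were mostly proximal in the authors' deposited table, with 5 higher in that class and Dach1 (4.46-fold) higher in the distal class. On the distal side of the authors' deposited table stood 3 loop of Henle and distal tubule genes, Emx2 (14.2-fold), Wfdc2 (8.18-fold) and Irx3 (1.91-fold), and the parietal genes Prom1 (21.2-fold) and Cav1 (4.96-fold) beside Lhx1. Stromal list genes were divided in the authors' deposited table, with Meis2 (8.88-fold) and Meis1 (8.61-fold) higher in the proximal and Aldh1a2 (8.86-fold) higher in the distal class. No immune, proximal tubule or housekeeping list gene had a fold among the 787 genes of the authors' deposited table, where chance gives only 0.651, 0.456 and 0.781, so their absence says little. The smallest fold in the authors' deposited table was 1.22, and how its genes and its 28 cells were chosen is not given in the sources used here.

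Clustering without class labels separated a larger cluster from a smaller mixed set, which did not hold together in every setting. The mean silhouette was highest with 2 clusters, at 0.0995, against 0.0994 with 3 and 0.0358 or less with 4 to 6, so all partitions were weak. The larger cluster held 43 cells and was led by the serine synthesis gene Phgdh (mean RPKM 168 ± 197, SD, n = 43 cells, against 2.33 in the other cells), Npy, the S phase gene Rrm1, the mitotic kinase Pbk, Clu, Ncs1, Bccip and Mad2l1. The smaller held 14 cells and was led by Sepp1 (mean 1329 ± 2015, SD, n = 14 cells, against 46.0), the lysozyme gene Lyz2, Dhrs3, Hexa, Abcg1, Apoe, Tyrobp and Sat1. Without the 6 cells with the most detected genes, the division into 2 gave 46 and 5 cells (adjusted Rand index 0.326 against the main division), and the 5 were the macrophage-like cells described next, so the rest of the mixed set joined the larger cluster. With 3 clusters, a setting added after the data were seen, these 14 cells parted into 9 and 5. The 5 cells, macrophage-like by the immune markers fixed beforehand, were led by Tyrobp (mean 2933 ± 1174, SD, n = 5 cells, against 1.03 in the other cells), Apoe (6274 against 11.7), Lyz2 (3044 against 10.6), Cd68 (1953 against 0.860), C1qb (2100 against 4.59), Ctss, Pf4 and Fcer1g. Pax8 was at most RPKM 1.99 in these 5 cells, and none of them was among the 28 cells of the authors' deposited table. The 9 cells were led by Nfkbia, Timp3, Vim, BC017643, Synpo, Frem1, Zscan21 and Cnn2 and were left unnamed. Early nephron genes were not confined to the larger cluster: 7 of these 9 cells had Pax8 between RPKM 112 and 1160. Of these 7, cell 52, which is among the 28 cells of the authors' deposited table, had the highest Sox9 (RPKM 355), Papss2 (508) and Pou3f3 (271) of all cells, genes chosen here after their values were seen. Cell 52 also had the fewest detected genes (2809) and an estimated 0.517 M reads, so these levels are uncertain. Leading genes describe the clusters that they helped to form.

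**Figure D4:**
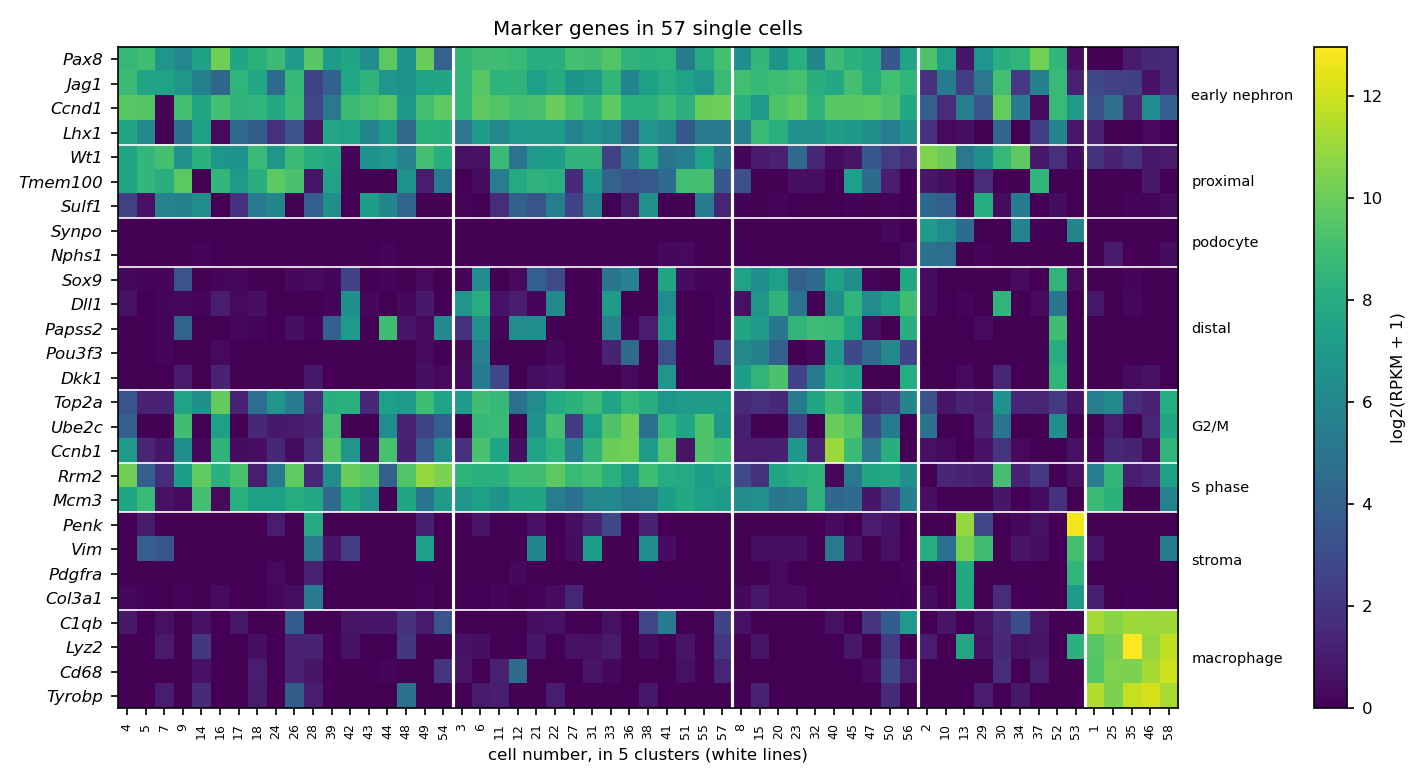
Levels of 27 marker genes (y axis, grouped by list) in 57 cells (x axis, cell numbers, ordered by 5 clusters parted by white lines), coloured by log2(RPKM + 1). Macrophage genes fill the last 5 cells, distal genes such as Dkk1 and Papss2 are strongest in the third cluster of 10 cells, and Pax8 is low in cells 13 and 53 of the cluster of 9.

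The genes that varied most from cell to cell beyond their mean included Apoe, Lyz2, Tyrobp and Cd68, which led the macrophage-like cells. The first 12 of 5607 ranked genes were Apoe, Penk, Lyz2, LOC100503946, Ftl1, Sepp1, Tyrobp, Tmsb4x, Cd68, Ctsb, Mal2 and Sat1. Apoe had a mean RPKM of 561 ± 2207 (SD, n = 57 cells) and exceeded RPKM 100 in 6 cells. The enkephalin gene Penk had a mean of 155 ± 909 and exceeded RPKM 100 in 3 cells, with a maximum of 6631 in cell 53. Mal2 exceeded RPKM 100 in 1 cell, where it reached 1700. Ranking by the variance of log2(RPKM + 1) kept 3 of the 12 genes, and Ftl1 and LOC100503946 have near-identical copies that can share reads.

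Sex-linked transcripts were unevenly distributed over cells of a pool whose sex the labels give as unknown. A Y-linked gene was detected in 13 cells (Ddx3y in 11, Eif2s3y in 9, Uty in 7 and Kdm5d in 3) and Xist, the RNA that silences an X chromosome in female cells, in 51 cells. Of the cells, 44 had Xist alone, 6 had a Y-linked gene alone and 7 had both, and none had neither. At RPKM 5 or more the counts were 37 with Xist alone, 9 with a Y-linked gene alone, 4 with both and 7 with neither. Cell 3 had Ddx3y at RPKM 140 with Xist at 0.675, and cell 30 had Xist at 272 with no Y-linked gene. Cells of both kinds argue for male and female cells in the pool. Above 0 all 57 cells had Xist, also the 20 with a Y-linked gene, so a low level of Xist does not give the sex of a cell. The 3 Y-linked genes found in at least 5 cells had a mean rho of 0.446 (percentile 100).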

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

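The settings without the cells of low Pax8, with 3 clusters and with 5 clusters were chosen after the results were seen. No paired analysis was possible because all cells belong to 1 group. The 787 genes of the authors' classes have no alternative value, since settings for the classes need the class of each cell and were not run. Over all listed genes, 919 shares of cells stayed within their 95% intervals under the alternatives and 166 left them, 110 of these with detection above 0 and 44 at RPKM 5. The median number of genes per cell was 5858 above 0, 3392 at RPKM 5 and 4356 after scaling by the upper quartile, all within 1.5 times the 4307 reported. Depth limits most the genes near RPKM 1, which is less than 1 read of a 2 kb gene in the shallowest cell. Differences that follow from a looser or stricter threshold come from its construction, and for the other settings the cause was not tested.

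With detection above 0 the share of cells with at least 2 members was 93.0% for nephron progenitor, 100% for distal renal vesicle, proximal renal vesicle and podocyte, 50.9% for proximal tubule, 63.2% for distal tubule, 98.2% for stroma and 77.2% for immune genes. It was 66.7% for nephron progenitor, 93.0% for renal vesicle, 80.7% for distal renal vesicle, 35.1% for distal tubule, 61.4% for stroma and 15.8% for immune genes at RPKM 5. Joint detection above 0 was 50.9% for podocyte with proximal tubule, 63.2% for podocyte with distal tubule, 100% for proximal with distal renal vesicle, 93.0% for progenitor with podocyte and 98.2% for renal vesicle with stroma, and at RPKM 5 the same pairs gave 12.3%, 33.3%, 71.9%, 63.2% and 57.9%. With 1 member asked for, the first 3 pairs gave 63.2%, 75.4% and 98.2% and the last gave 96.5%, and with 3 members the 5 pairs gave 5.26%, 22.8%, 77.2%, 50.9% and 43.9%. Xist was found in 100% of cells above 0 and in 71.9% at RPKM 5. Cells with both Xist and a Y-linked gene made 35.1% above 0, and cells with neither made 12.3% at RPKM 5.

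The coherence of the distal renal vesicle and immune lists was 0.377 and 0.887 by Pearson's r, and 0.390 and 0.481 over members detected in at least 10 cells. With the number of detected genes regressed out, the mean rho was 0.328 for distal and 0.069 for proximal renal vesicle, 0.385 for G2/M and -0.038 between proximal and distal. Without the 6 cells with the most detected genes it was 0.484 for G2/M. Of 22 coherence values, 8 moved by more than the SD of their random lists with Pearson's r, 9 with detected genes regressed out and 11 without the 7 cells of low Pax8. Without these 7 cells the mean rho was 0.049 for proximal renal vesicle, 0.133 for podocyte, 0.293 for immune genes and -0.067 between proximal and distal, while 90% of cells had at least 2 progenitor genes, 100% had at least 2 podocyte genes and 90% had both. The silhouette favoured 3 clusters instead of 2 with pseudocount 0.1, with 1000 variable genes, with every gene that passed the filter and without cell 41, the single cell more than 3 scaled MADs from the median number of genes. The added settings had 3 and 5 clusters by construction. In all 6 settings fixed beforehand, a division into 3 placed the 5 macrophage-like cells together. Of the first 12 overdispersed genes 3 were kept when ranked by the variance of log2(RPKM + 1), and all 12 with a mean RPKM of 1 or more as the filter.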

Other observations

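The tests on index sharing and on an even background were written before their results were seen. The other 5 tests, the division into 5 clusters, the list of imprinted genes and the choice of single cells described here followed after the data were seen.

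With 5 clusters the larger cluster of 43 cells fell into 3 parts. A part of 18 cells was led by H19 (mean RPKM 453 against 122 in the other cells), Npy, Wt1 (240 against 149), the replication genes Mcm2 and Rfc2, Mmp2, Tmem100 (233 against 70.8) and Ahsa1. A part of 15 cells, with a median of 5419 detected genes, was led by Pbk (344 against 125), Tacc3, the G2/M genes Ube2c (323 against 81.6), Aurkb and Ccnb1, Fdps, Kif22 and Racgap1. A distal renal vesicle-like part of 10 cells was led by Dkk1 (187 against 11.1), Papss2 (210 against 35.3), Dll1 (170 against 24.5), Enc1, Sox9 (94.4 against 16.1), Dalrd3, Rab3ip and 2900092D14Rik. Within the unnamed 9 cells, cells 2, 10 and 34 combined strong Wt1 (RPKM 1382, 1019.5 and 865) with the podocyte gene Synpo (142, 77.3 and 56.6). Cells 13 and 53 instead had Penk (1909 and 6631), Pdgfra (237 and 365) and the collagen gene Col3a1 (231 and 123), with Pax8 at 0.744 and 0.437. In cells 52 and 30, which had the fewest reads, LOC100503946 took 10.52% and 8.19% of all RPKM.

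Several imprinted growth genes, a list made after H19 had been seen to lead a cluster, were found in most cells. H19 was found in 45 cells at a mean RPKM of 227 ± 429 (SD, n = 57 cells), Mest in 46 (mean 224 ± 299), Grb10 in 47, Cdkn1c in 44, Igf2 in 36, Peg3 in 33, Ndn in 32 and Plagl1 in 4.

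Values of the same genes and cells differed between both deposited tables. Of 13519 values, 28.2% lay within 0.1% of the commonest ratio of their cell and 71.6% lay below it, which argues against 1 scale factor per cell, and 1.73% of gene pairs within a cell changed order, which argues against a rescaling that keeps the order of genes. Removal of whole reads, with more lost from abundant genes, as in the removal of duplicate reads, is a candidate explanation: 97.8% of 183 low values that shrank were whole reads in both tables (within 0.1 read). The median share kept was 100% below RPKM 1, 92.6% from 1 to 10, 83.0% from 10 to 100, 69.6% from 100 to 1000 and 37.9% above, with 34.5% of reads removed in the median cell (29.1 to 42.3%) if values that kept the commonest ratio lost no read. No biological explanation was tested, since the cells are the same.

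Macrophage transcripts were also found outside the 5 macrophage-like cells, with Lyz2 at RPKM 304 in cell 53, C1qb at 129 in cell 56, Csf1r at 113 in cell 26 and Cd14 at 105 in cell 40, above its mean of 12.2 in the macrophage-like cells. An even background of RNA from macrophages is argued against for the list as a whole, since the mean outside, as a percent of the mean inside, was 811 times higher for Cd14 (16.6%) than for C1qc (0.0205%). Without the highest cell of each gene the highest and lowest percents still differed 132 times, but this rested on Ptprc (0.987%), with Lyz2 next (0.159%). Fcgr3, C1qc, Csf1r, C1qa, Tyrobp and Cd68 then lay between 0.0075 and 0.0223%, so a low background shared by these genes stays open. Carry-over between libraries that share an index stays open: the median summed level was 0.787 times as high in 37 cells sharing an index with a macrophage-like cell (2.16) as in 15 sharing none (2.75). That ratio lay below the bound of 1.2 set against carry-over, but the bootstrap interval of the smaller group's median, added after the value was seen, ran from 0 to 41.8 and leaves both readings possible. No biological explanation was tested.

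In 9 cells Wt1 and a distal gene (Sox9, Dll1, Papss2, Pou3f3 or Dkk1) both reached RPKM 20, where independence of the 36 and 23 cells concerned gives 14.5. Capture of 2 cells in 1 chamber stays open for these cells: 3 of the 9 (33.3%), against 0.947 expected, were among the 6 cells with the most detected genes, which is too few to decide. Of these 3, cells 22 and 41 also had Xist (RPKM 5.81 and 7.18) with a Y-linked gene (Eif2s3y at 28.2 and Uty at 19.8). Capture of 2 cells of different sex, or carried-over reads, would give this. The others of the 9 had no Y-linked gene at RPKM 1 or more, but 2 cells of the same sex would not show in this way. Carry-over of reads between libraries stays open too: the weaker gene stood at a median of 9.35% of its highest level in any cell, but the choice of cells at RPKM 20 or more allows no percent below 1.45, so the bound of 1 set for carry-over was out of reach. A cell state between proximal and distal was not tested, because the labels give a single group.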
